A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

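Total RNA of budding yeast cells of the BY4741 background, wild type or lacking VPS1, was measured on Affymetrix yeast expression arrays, with 3 arrays per strain from cultures that the series design describes as independent biological replicates. Per the labels' protocols, cells grew at 30 degrees in a supplemented minimal medium, RNA was purified on columns, and biotinylated cRNA was made from 100 ng of total RNA by in vitro transcription from the 3' end. The deposited values are on a log2 scale, 1 value per probe set and array. The submitters' processing notes name GCOS, RMA and limma; their versions, roles and order are not given in the sources used here, and neither is the step at which arrays were scaled to each other. The scanner images were not used here. Arrays have no read depth, so the number of arrays limits the precision.

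The values table holds 10928 probe sets. The annotation given for the platform named 7244 of them with 1 gene symbol, 1 with several and 3470 with none, and the remainder were 166 control and 47 reporter probe sets. Symbols were matched to the yeast gene table of the S288C R64 assembly, which served for names, chromosomes and neighbouring genes. Of the named probe sets, 5498 matched a Saccharomyces cerevisiae gene and 1746 carried names absent from that table; the latter served as a measure of background. A gene with several probe sets, of which there were 47, was represented by the probe set with the highest mean over the 6 arrays, which left 5449 genes. No mitochondrially encoded gene was among them. The background level of an array was the 95th percentile of these 1746 probe sets on it, between 3.53 and 3.59 on the quantile scale. Where every array of 1 strain lay at or below its background level, the difference is given as at least N-fold, computed against that level, with the fitted adjusted p. For group means in the rule for named genes, the level was the 95th percentile of the probe sets' means over arrays, 3.50.

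The test of each gene was the moderated test of limma 3.58.1 in R 4.3.3 (lmFit and eBayes, vps1 deletion minus wild type, 2-sided, 3 against 3 arrays), with Benjamini-Hochberg adjustment over the 5449 genes and a threshold of 0.05; a further count required an absolute log2 difference of at least 1. This fit was fixed before the data were examined, on the values as deposited. The values then showed that the vps1 deletion arrays lie about 0.5 above the wild type arrays over the whole range, control probe sets included. Every change of a gene or list is therefore given relative to that shift, from the same fit after quantile normalization of all 10928 probe sets across the 6 arrays, named the quantile scale. Quantile normalization was among the alternatives listed beforehand, while its use as the scale of the reported changes was chosen after seeing the data; a change common to most genes cannot be seen on it. Counts of changed genes and called lists on the deposited scale are printed as well.

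Gene lists, 50 in all, were fixed before the data were examined, from textbook knowledge of yeast pathways. They hold 1627 names, of which 1619 matched a gene, and 1535 different genes were measured. MLP1, entered among the cell wall integrity targets, and TAF1, entered in the iron list, are older names that now denote other genes. Lists with at least 5 measured members, 47 of them, were tested with limma's camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists; a list is called higher or lower at an adjusted p under 0.05. Camera compares the changes of a list with those of the other genes tested, so a list called lower can still lie above wild type. Camera with a correlation estimated per list, fry and camera on ranks were alternatives. None of the 47 lists passed with an estimated correlation, where 6 had an unadjusted p under 0.05; fry called 13 of the 19 lists in the same direction. A member rose or fell if it passed the test of single genes over all genes tested; counts adjusted over the list alone are given beside.

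The genes named are the members of the lists on the VPS1 locus, the BY4741 marker loci and the a-specific and alpha-specific genes; the 12 largest rises and the 12 largest falls among genes past the threshold whose groups do not overlap and whose higher group mean is above background; and, for each other list described, up to 4 members with the smallest p and, in the called lists, members that passed in the direction opposite to the list. The rule was fixed before the data were examined. On the deposited scale it names the same 12 rises and 12 falls. Any other gene is said to be chosen after its values were seen. A member that this rule names in the list of cell wall integrity signalling components is not reported here.

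Replicate numbers are shared between the strains in the labels. Deviations from the strain means correlated over genes at 0.67, 0.65 and 0.29 between arrays of the same number, all above 0.1, while the other pairs lay between -0.63 and 0.23. The pairing thus comes from the values, not from a label that names a shared day, and the fit with the replicate number as a block is printed beside a result where it changes the call or moves a count by over 1.5 times.

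The procedure was tested on simulated data with a shift of 0.5 between strains over 5449 genes. On the deposited scale 84.1% of the 5249 unchanged genes were called. On the quantile scale 0.133% of them were called. Of genes with simulated log2 changes of 0.5, 1 and 2, 41.8%, 86.6% and 97.0% were recovered. A raised list was called and 0 of 40 unchanged lists were. The simulated genes varied independently, with no replicate effect, so the 0 of 40 does not bear on false list calls among correlated genes. Further alternatives were median centring, leaving out dim probe sets, testing every probe set that is no control, the mean of a gene's probe sets, a variance trend with robust estimation, array weights, an unmoderated test, other thresholds, and leaving out each array in turn. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.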

Results

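Transcript levels were compared between wild type budding yeast and a strain lacking VPS1, which encodes a dynamin-like GTPase of vacuolar protein sorting, endocytosis and peroxisome division. The comparison asks which genes, including those of signalling pathways, change when this dynamin is missing in cells under normal growth. Each strain was represented by 3 arrays, and 5449 genes were measured. Arrays of a strain correlated over genes at r between 0.985 and 0.994 in wild type and between 0.991 and 0.994 in the deletion strain, and at 0.964 to 0.975 between strains. The median SD of a gene over the 3 arrays was 0.153 in wild type and 0.128 in the deletion strain on the log2 scale, and the median SE of a difference was 0.120.

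As deposited, the vps1 deletion arrays lay above the wild type arrays over the whole range of values. The median log2 difference was 0.51 over the 5449 genes, 0.48 over the 1746 probe sets with names absent from the yeast gene table, and 0.60 over the 27 hybridization control probe sets, each of which was higher in the deletion strain. On these values 4194 genes passed the test, 4142 of them higher and 52 lower. All changes below are relative to this shift, on values brought to 1 distribution by quantile normalization, where the median difference of all genes was -0.04. The 3' minus 5' signals of ACT1, TDH1, WBP1, SPT15 and RIP1 differed between strains by -0.10 to 0.11 on the log2 scale, with exact permutation p of 0.3 to 0.8 where 0.1 is the smallest that 3 against 3 arrays allow. Of the 166 control probe sets, 3 passed the test and were at least 2-fold lower in the deletion strain, all of them for ribosomal RNA.

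**Figure D1:**
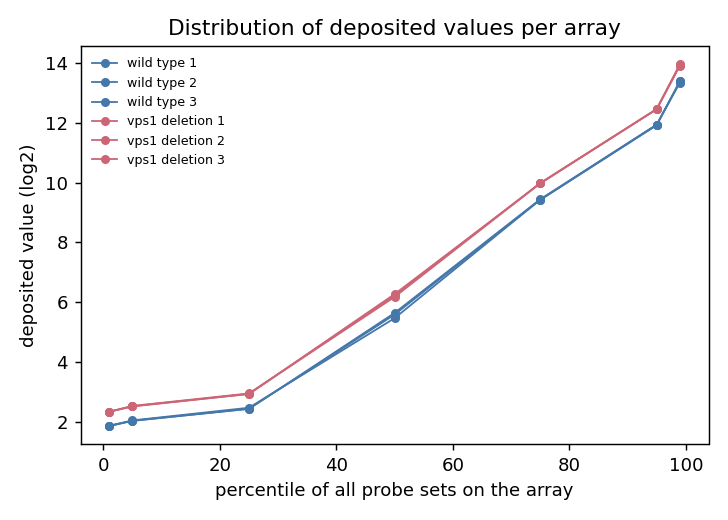
Percentiles of all probe sets (horizontal axis) against the deposited value on the log2 scale (vertical axis), with 1 line per array, 3 wild type in blue and 3 vps1 deletion in red. The lines of a strain nearly coincide, and the deletion arrays lie higher by 0.47 at percentile 1 and by 0.56 at percentile 99.

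VPS1 transcript was lost in the deletion strain. Its level was 10.08 ± 0.21 (log2, SD, n = 3) in wild type and 2.39 ± 0.16 in the deletion strain, where it lay below the background level on every array, at least 91.5-fold lower (adjusted p = 1.65e-07). Of its neighbours on chromosome XI, PAP1, the poly(A) polymerase, rose by 0.63 ± 0.09 (log2, SE) and OSH6, an oxysterol-binding protein homologue, by 0.55 ± 0.10, while DID4 (0.20 ± 0.10) and MET14 (0.07 ± 0.18) did not pass. Among the marker loci of the strain background, URA3 and MET17 were below background in both strains. The signal of the LEU2 probe set fell by 0.93 ± 0.14, from a low level of 4.57 in wild type to 3.64 in the deletion strain, near background. Whether this signal comes from LEU2 transcript was not tested. HIS3 was well above background, at 10.78 in wild type and 10.63 in the deletion strain, a difference of -0.15 ± 0.15. In the list of VPS1 and its neighbours 2 genes rose and 1 fell, of 5 measured, the same number as adjusted over the list alone; its median was 0.20 and its mean, which depends on the background through VPS1, -1.25, and the list was not called (camera adjusted p = 0.541). Of the 4 marker loci the signal of 1, LEU2, fell, as also when adjusted over the list alone.

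In the vps1 deletion strain 25 of 34 genes of the sterol list and 9 of 16 of anaerobic cell wall mannoproteins rose, DAN1 in both, while 5 of 7 a-specific mating genes and 14 of 37 of sulphur assimilation fell. No list passed a test with an estimated correlation between genes (smallest adjusted p 0.191). Relative to the shift, 711 genes passed the test, 369 higher and 342 lower; 159 changed at least 2-fold, 117 of them higher and 42 lower, against 472 as deposited, 459 higher and 13 lower. With the replicate number as a block 1676 genes passed, 784 higher and 892 lower, and all 711 were among them. The count was 351 without wild type replicate 2, and 358, 446 and 322 without vps1 deletion replicate 1, 2 or 3; no called gene changed sign.

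Among the 12 largest rises were DAN1, DAN4, TIR1 and TIR3, cell wall mannoproteins that yeast makes in the absence of oxygen. DAN1 was below background in wild type and at 8.55 ± 0.52 (log2, SD, n = 3) in the deletion strain, at least 31.9-fold higher (adjusted p = 2.45e-05), and TIR1 rose by 4.29 ± 0.18 (log2, SE), DAN4 by 4.19 ± 0.32 and TIR3 by 3.07 ± 0.20. Genes of lipid metabolism were also among the 12. HES1, an oxysterol-binding protein homologue, rose by 4.92 ± 0.11, YSR3, a phosphatase of sphingoid base phosphates, by 5.05 ± 0.10, and RTA1, which confers resistance to aminocholesterol, by 3.01 ± 0.18. PHO89, a sodium-phosphate cotransporter, rose by 3.86 ± 0.45, SET4, a SET domain protein, by 4.30 ± 0.19, and FHN1, a plasma membrane protein related to NCE102, by 3.24 ± 0.27. YMR317W and PBI1 had rises of 5.92 ± 0.24 and 5.34 ± 0.10. The adjusted p of these 12 genes lay between 1.65e-07 for PBI1 and YSR3 and 0.00188 for PHO89.

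The 12 largest falls, after VPS1, were led by TIP1, another cell wall mannoprotein, which fell by 2.75 ± 0.12 (log2, SE, n = 3 per strain). RSB1, a membrane protein for sphingoid base resistance, fell by 2.22 ± 0.14, and ELO1, a fatty acid elongase, fell by 1.82 ± 0.15. The weak acid exporter PDR12 fell by 1.88 ± 0.11. OPT2 and OPT1, oligopeptide transporters, fell by 2.04 ± 0.17 and fell by 1.60 ± 0.12. IMD2, an IMP dehydrogenase of guanine nucleotide synthesis, fell by 1.84 ± 0.14, on a probe set whose suffix marks possible signal from other genes. The transcriptional regulator RPI1 fell by 1.81 ± 0.15, and WSC4, of the cell wall sensor family, fell by 1.74 ± 0.18. YBL029W fell by 2.08 ± 0.19 and YGR035C fell by 1.65 ± 0.23. The adjusted p of these 11 genes lay between 2.07e-05 for TIP1 and 0.00379 for YGR035C.

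**Figure D2:**
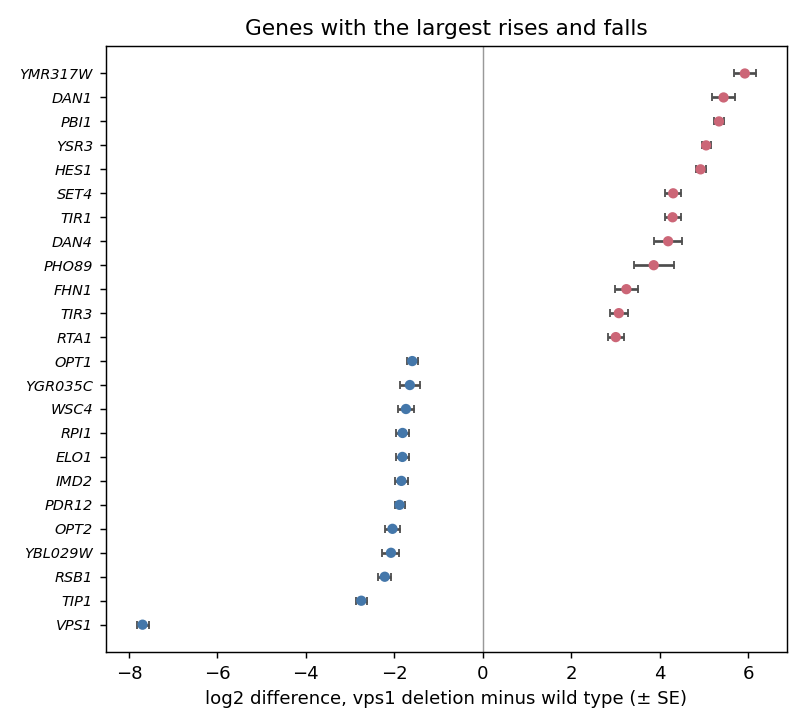
Log2 difference, vps1 deletion minus wild type, on the quantile scale (horizontal axis) for the 12 largest rises in red and the 12 largest falls in blue, as points with bars of 1 SE from the fit over 3 arrays per strain. The rises range from 3.01 for RTA1 to 5.92 for YMR317W; VPS1 in the deletion strain and DAN1 in wild type were below background, so their points depend on the background.

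Most genes of the ergosterol list rose. It holds genes of sterol synthesis with some of sterol transport and regulation and DAN1, which is also in the anaerobic cell wall list. Of 34 measured, 25 rose, 1 fell and 8 did not pass; adjusted over the list alone 29 rose and 1 fell. The list was called higher (camera adjusted p = 1.10e-20), though not with an estimated correlation (adjusted p = 0.259 with an estimated correlation). ERG3, the sterol C-5 desaturase, rose by 1.74 ± 0.10 (log2, SE) and ERG26, a sterol C-4 decarboxylase, by 1.40 ± 0.08, beside HES1 and DAN1 given above. ECM22, a transcription factor of sterol genes, fell by 1.02 ± 0.10. In the list of seripauperins and anaerobic cell wall mannoproteins 9 of 16 rose and none fell, 12 when adjusted over the list alone (camera adjusted p = 1.96e-10; adjusted p = 0.259 with an estimated correlation). The phospholipid and sphingolipid list had 4 members that rose and 6 that fell of 41, 6 and 8 adjusted over the list alone and 6 and 12 with the replicate number as a block, and was not called (adjusted p = 0.311). PDR16, a phosphatidylinositol transfer protein, fell by 0.80 ± 0.10 there, and YDC1, a ceramidase, rose by 0.79 ± 0.11.

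Cell wall integrity targets were higher. Of 39 measured, 18 rose and 1 fell, 22 and 2 adjusted over the list alone and 24 and 3 with the replicate number as a block (camera adjusted p = 7.32e-10; adjusted p = 0.479 with an estimated correlation). TIR1, given above and also in the anaerobic cell wall list, had the smallest limma p of these targets and rose by 4.29 ± 0.18. GSC2, a glucan synthase, rose by 2.77 ± 0.14, YPS3, a cell surface aspartic protease, by 2.40 ± 0.11, and PRM5 by 2.00 ± 0.12. The flocculin FLO11 fell by 0.48 ± 0.11. Calcineurin and Crz1 targets shared YPS3 and GSC2 and were also higher, with 10 that rose and 1 that fell of 23, 13 and 1 adjusted over the list alone and 13 and 2 with the block (adjusted p = 8.84e-06; adjusted p = 0.392 with an estimated correlation). PMC1, the vacuolar calcium pump, rose by 1.30 ± 0.13 and GYP7, a Rab GTPase activator, by 1.11 ± 0.12; CNA1, a catalytic subunit of calcineurin, fell by 0.40 ± 0.10. In the list of cell wall integrity signalling components, which shares 6 members with the targets, 4 of 30 rose and 1 fell, the same as adjusted over the list alone, and 7 rose and 3 fell with the block; it was not called (adjusted p = 0.217). Its kinase SLT2 rose by 1.18 ± 0.18 and the transcription factor RLM1 by 0.47 ± 0.09.

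Part of the iron, unfolded protein response, phosphate and induced stress genes rose too. In the Aft1 and Aft2 iron regulon 17 of 33 rose and 1 fell, 20 and 2 adjusted over the list alone and also with the replicate number as a block (camera adjusted p = 6.09e-08; adjusted p = 0.289 with an estimated correlation). TIS11, an mRNA-binding regulator of iron use, rose by 2.57 ± 0.14, and the siderophore transporters SIT1 and ARN1 rose by 1.67 ± 0.19 and 1.21 ± 0.11, while ISU2, an iron-sulphur scaffold, fell by 0.98 ± 0.14. In the unfolded protein response list 10 of 30 rose, 18 with the block and 17 adjusted over the list alone (adjusted p = 1.76e-07; adjusted p = 0.259 with an estimated correlation). EUG1, a disulphide isomerase, rose by 0.94 ± 0.12 and HAC1, the response's transcription factor, by 0.46 ± 0.10. Of the 21 genes of the PHO regulon 6 rose, 7 adjusted over the list alone, while 12 rose and 1 fell with the block (adjusted p = 5.49e-04, and 0.156 as deposited; adjusted p = 0.496 with an estimated correlation), PHM8, a lysophosphatidic acid phosphatase, by 1.45 ± 0.14. Genes induced in the environmental stress response rose in 14 of 69 cases; 31 rose and 9 fell with the block, and 15 rose and 1 fell adjusted over the list alone (adjusted p = 6.04e-06, and 0.959 as deposited; adjusted p = 0.682 with an estimated correlation). HSP78, a mitochondrial chaperone, rose by 1.21 ± 0.14. Hog1-dependent targets, 14 of which are also in the stress list, rose in 5 of 30 cases, 5 also adjusted over the list alone, while 10 rose and 5 fell with the block (adjusted p = 0.0163, and 0.919 as deposited; adjusted p = 0.708 with an estimated correlation), with DDR48 up by 0.97 ± 0.17. The Hog1 call was also lost without wild type replicate 2 (adjusted p = 0.197) and without vps1 deletion replicate 1 or 3 (0.0580 and 0.170).

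Genes of the vacuole and endocytosis were higher in part. From the share of all genes, 1.02, 3.12, 2.23 and 4.27 rises were expected among vacuolar hydrolases, endocytosis, autophagy and vacuolar protein sorting genes. In the list of vacuolar hydrolases 6 of 15 rose and 1 fell, 8 and 1 adjusted over the list alone and 10 and 1 with the replicate number as a block (camera adjusted p = 9.86e-05; adjusted p = 0.441 with an estimated correlation). AMS1, the alpha-mannosidase, rose by 2.38 ± 0.12 and PRB1, the vacuolar proteinase B, by 1.10 ± 0.16. YPS1, a cell surface protease that this list shares with the cell wall integrity targets, rose by 1.46 ± 0.12, while VTH1, a sorting receptor homologue, fell by 0.48 ± 0.10. Endocytosis and actin patch genes rose in 7 of 46 cases, 8 adjusted over the list alone and 21 with the block (adjusted p = 3.05e-06; adjusted p = 0.479 with an estimated correlation). The actin patch kinases ARK1 and PRK1 rose by 0.77 ± 0.14 and 0.49 ± 0.09. Autophagy genes rose in 4 of 33 cases, 4 adjusted over the list alone, while 12 rose and 2 fell with the block (adjusted p = 0.0101, and 0.0725 as deposited; adjusted p = 0.392 with an estimated correlation), ATG5 by 1.15 ± 0.13 and ATG22 by 0.83 ± 0.09. The vacuolar protein sorting list had 6 members that rose and 1 that fell of 63, 3 and 1 adjusted over the list alone and 12 and 6 with the block, and was not called (adjusted p = 0.158). PEP12, a syntaxin of the late endosome, rose by 1.14 ± 0.09 and GGA1, a clathrin adaptor, by 0.96 ± 0.13. Of the 12 dynamin-related and fission genes, MGM1, the mitochondrial dynamin of inner membrane fusion, fell by 0.49 ± 0.09, the sole change also when adjusted over the list alone, and 3 fell with the block (camera adjusted p = 0.621).

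The a-specific genes were lower. Of 7 measured 5 fell, and all 7 adjusted over the list alone (camera adjusted p = 1.16e-05; adjusted p = 0.289 with an estimated correlation). ASG7 fell by 1.34 ± 0.11, AGA2, the agglutinin subunit, fell by 1.37 ± 0.15, the pheromone gene MFA2 fell by 0.85 ± 0.12, the pheromone protease BAR1 fell by 0.57 ± 0.09, and the receptor STE2 fell by 0.47 ± 0.09; STE6 (-0.41 ± 0.13) and MFA1 (-0.32 ± 0.12) passed with the replicate number as a block (adjusted p = 0.0124 and 0.0253). Of 4 alpha-specific genes, STE3 rose by 0.54 ± 0.14, SAG1 differed by 0.37 ± 0.12, which passed with the block (adjusted p = 0.0105), and MF(ALPHA)1 and MF(ALPHA)2 by -0.38 ± 0.18 and -0.13 ± 0.15; 2 rose adjusted over the list alone, as with the block. Pheromone-induced genes, 6 of them a-specific, fell in 18 of 38 cases and rose in 8, 21 and 9 adjusted over the list alone. The list was not called (camera adjusted p = 0.237). As deposited it was called lower than the other genes (camera adjusted p = 4.87e-06), with a mean of 0.49 above wild type. PRM4 and PRM10 rose by 2.96 ± 0.13 and 1.25 ± 0.11. Of 29 pheromone and filamentous signalling components 8 fell, the same number as adjusted over the list alone, while 2 rose and 9 fell with the block (adjusted p = 0.170), among them the transcription factor STE12, which fell by 0.48 ± 0.08, and the kinase FUS3, which fell by 0.54 ± 0.11. On the deposited values STE2, STE6 and MFA1 of the a-specific genes lay above wild type by 0.049, 0.13 and 0.22, and STE12 and FUS3 by 0.061 and 0.0088.

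Part of the genes of sulphur, purine and amino acid metabolism, of the G2 and M phases and of ribosome biogenesis fell. Sulphur assimilation and methionine genes fell in 14 of 37 cases, and adjusted over the list alone 15 fell and 2 rose, and 18 and 2 with the replicate number as a block (camera adjusted p = 2.63e-05; adjusted p = 0.441 with an estimated correlation). The S-adenosylmethionine and S-methylmethionine permeases SAM3 and MMP1 fell by 1.44 ± 0.13 and fell by 1.42 ± 0.13, beside OPT1. Purine genes fell in 6 of 29 cases, 9 adjusted over the list alone and 12 with the block (adjusted p = 1.30e-04; adjusted p = 0.496 with an estimated correlation), and GCV2 of glycine cleavage fell by 1.17 ± 0.17. Gcn4 targets of amino acid synthesis fell in 8 of 68 cases, 4 adjusted over the list alone, while 26 fell and 2 rose with the block (adjusted p = 6.33e-04, and 0.0757 without wild type replicate 1; adjusted p = 0.695 with an estimated correlation), and GLT1, glutamate synthase, fell by 0.85 ± 0.14. Genes of the G2, M and M/G1 phases fell in 11 of 39 cases, 17 adjusted over the list alone and 20 with the block (adjusted p = 3.12e-06; adjusted p = 0.191 with an estimated correlation), HOF1, a cytokinesis protein, fell by 0.90 ± 0.09, and the polo kinase CDC5 fell by 0.67 ± 0.09. Ribosome biogenesis genes fell in 9 of 102 cases, against 6.40 expected from the share of all genes, 0 adjusted over the list alone, where 24 had an unadjusted limma p under 0.05, and 32 with the block (adjusted p = 5.91e-06; adjusted p = 0.534 with an estimated correlation), and NOP13 fell by 0.51 ± 0.10. Pleiotropic drug resistance genes fell in 11 of 28 cases and rose in 2, 11 and 4 adjusted over the list alone and 12 and 7 with the block (adjusted p = 0.0379; adjusted p = 0.534 with an estimated correlation). The drug resistance call was lost with the block (adjusted p = 0.0727), on ranks (0.107), and without wild type replicate 1 (0.0974) or vps1 deletion replicate 3 (0.0823). The exporter PDR15 fell by 1.25 ± 0.12, while RTA1 and the transporter HXT11 rose, the latter by 0.85 ± 0.20.

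**Figure D3:**
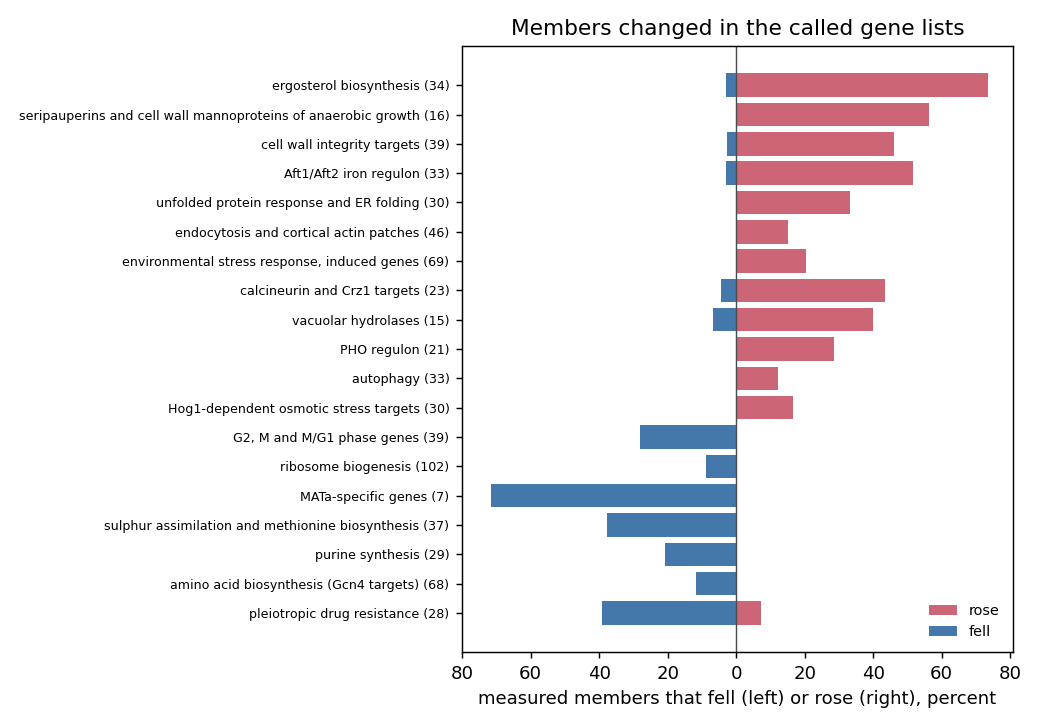
Share of measured members, in percent, that fell (blue, left) or rose (red, right) in the deletion strain for the 19 lists called by camera, 12 higher and 7 lower, with the number measured in brackets. As deposited 20 lists were called, 9 higher and 11 lower relative to the other genes. None of the 19 calls holds with an estimated correlation.

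Other signalling, energy and transport lists were not called. Hexose transporter, TCA and oxidative phosphorylation lists were called lower as deposited relative to the other genes. Their deposited means were 0.41, 0.44 and 0.44 above wild type, against a median of 0.51 over all genes. Of 26 HOG pathway components the phosphatase PTP2 rose by 0.97 ± 0.12 and the transcription factor SMP1 by 1.25 ± 0.16, the same number adjusted over the list alone, while 5 rose and 2 fell with the replicate number as a block (camera adjusted p = 0.311). Of 54 TORC and PKA components 3 rose and 4 fell, the same adjusted over the list alone and 7 and 7 with the block (adjusted p = 0.895; median 0.024, mean -0.012), with YPK1, a kinase of plasma membrane homeostasis, up by 0.98 ± 0.12, while RAS1 fell by 0.79 ± 0.10. Hexose transporters rose in 4 and fell in 5 of 21 cases, 4 and 7 adjusted over the list alone (adjusted p = 0.312; called lower as deposited, adjusted p = 0.00605). HXT5 rose by 1.52 ± 0.27 and HXT4 fell by 1.12 ± 0.13. Genes of the TCA and glyoxylate cycles fell in 7 and rose in 1 of 41 cases, 8 and 2 adjusted over the list alone and 14 and 5 with the block (adjusted p = 0.704; called lower as deposited, adjusted p = 0.0108). Of 43 oxidative phosphorylation genes 2 fell in both counts, while 10 fell and 2 rose with the block (adjusted p = 0.666; called lower as deposited, adjusted p = 0.0308), and the regulator HAP4 fell by 1.09 ± 0.14. Heat shock chaperones rose in 3 and fell in 2 of 30 cases, 6 and 3 adjusted over the list alone and 7 and 6 with the block (adjusted p = 0.704; median -0.09, mean 0.15), with BTN2 up by 1.67 ± 0.12. Peroxisome and beta-oxidation genes rose and fell in 1 case each of 31, the same adjusted over the list alone, while 6 rose and 3 fell with the block (adjusted p = 0.691; median -0.01, mean 0.01). POT1, the thiolase, rose by 0.91 ± 0.15 and PEX2 fell by 0.50 ± 0.12. Of 127 ribosomal protein genes 0 passed limma's test, where 1 had an unadjusted p under 0.05 and 2 rose with the block (camera adjusted p = 0.737; called higher as deposited, adjusted p = 9.23e-05). Of 41 proteasome genes 0 passed, where 2 had an unadjusted p under 0.05 and 1 rose with the block (adjusted p = 0.972). Of 24 V-ATPase genes 0 passed, also without adjustment and with the block (adjusted p = 0.906). Adjusted over the list alone, 0 passed in each of these lists, and the signs of their medians or means differed from that of the test.

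The camera calls rank lists under a fixed correlation between genes, and none passed with an estimated one. Another split of the same 6 arrays into 3 and 3 gave as many as 19 list calls, though it mixes the strains and keeps part of their difference. Changes shared by most genes cannot be read from the quantile scale.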

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

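The tests of the explanations below were all chosen after the results were seen. In probe sets outside the comparison of genes, 1 of the 47 reporter probe sets stood at 2.54 ± 0.14 (log2, SD, n = 3) in wild type, below background, and at 13.49 ± 0.05 in the deletion strain, at least 977-fold higher; the annotation used here names no target for it. A second reporter probe set, which shares the identifier of this one, stood at 3.37 ± 0.16 in wild type, also below background. In the deletion strain it was at 3.91 ± 0.14, at least 1.28-fold higher. Among the 3470 unnamed probe sets, 13 were at least 2-fold higher in the deletion strain and 1 was at least 2-fold lower.

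The first pattern is the offset of about 0.5 between the deposited arrays of the strains. More RNA of most genes in the deletion strain does not account for all of it, since the hybridization controls, which are added in fixed amounts, lay above wild type by a median of 0.60, and so did background probe sets by 0.48. That same control median is consistent with the strains having been put on different scales in processing. A difference in RNA amount on top of the scale stays open, since values scaled by strain cannot show it.

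The second pattern is the rise of sterol and anaerobic cell wall genes. Low oxygen in the deletion cultures would raise the genes that Rox1 represses, and the median of 6 of them was -0.37. ROX1 itself is among the 6, at -0.30 ± 0.21, and its own level is no test of low oxygen. HEM13 alone rose, by 0.68 ± 0.18, and AAC3 fell by 0.56 ± 0.11. COX5B differed by -0.70 ± 0.20 and passed with the replicate number as a block (limma adjusted p = 8.78e-04). Cross-hybridization between paralogs is argued against by probe sets without a shared-target suffix. They measured all 34 genes of the sterol list, hence also the 25 that rose, and 9 of the 16 cell wall genes. For the sterol genes the argument thus rests on the probe design alone, with no shared probe sets to compare. Of these 9 cell wall genes 6 rose, and the median of the 9 was 1.25. The other 7 cell wall genes were not tested for it. The gap between strains as deposited varied by 0.204 over percentiles 1 to 99, so a scale that varies with signal was small there. The list medians of 0.85 and 0.59 are on the quantile scale. Quantile normalization removes such a gap, so the 0.204 does not test them. A change of sterol balance in cells without VPS1, which the strain comparison could bring, is a hypothesis that no test here addressed.

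The third pattern is the fall of a-specific genes. An alpha culture, or a mixture with alpha cells, is argued against by MF(ALPHA)1 and MF(ALPHA)2, which are abundant in alpha cells. They stood at 3.95 and 4.89 in the deletion strain, and the higher of their differences was -0.13. They do not bear on a mixture with cells that express neither gene, which was not tested. The deposited gap, which varied by 0.204, does not test the a-specific median of -0.57 either, which is also on the quantile scale. The rise of STE3 by 0.54 goes with alpha cells, as does the difference of SAG1, 0.37 (limma adjusted p = 0.0105 with the replicate number as a block). A mixture would lower the RNA of each a-specific gene alike, and their differences ranged from -0.32 to -1.37. Array signal need not follow RNA equally for every gene, so this range does not decide on a mixture. Lower output of the pheromone pathway may contribute: of 28 pheromone-induced genes outside the a-specific and cell wall integrity lists 13 fell and 5 rose, which leaves it open because members moved both ways. A direct effect of the deletion on these genes was not tested.

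The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every other split mixes both strains in each group, so the strain difference widens the spread within groups and partly remains between them. Counts of the other splits are therefore no measure of chance, for genes or for lists. The real split, which was the 1 split with a count as large, gave 4194 changed genes as deposited and 711 on the quantile scale, and 472 and 159 at least 2-fold; the highest count of any other split was 0 in each case, where up to 841 genes had an unadjusted limma p under 0.05 on the quantile scale and 160 as deposited. For gene lists called by camera the real split gave 20 as deposited and 19 on the quantile scale, the highest other split gave 22 and 19, and 3 of the 10 splits had a count as large on either scale. Of the splits that part all 3 pairs of replicate numbers, as the real one does, 1 other gave 22 and 19 lists, and the others gave 13 and 8, and 18 and 16; the 6 splits that part 1 pair gave up to 20 and 19.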

How the results depend on the processing

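Every alternative on the quantile scale was chosen after the data were seen as a setting for that scale. Signal over background limits genes below the level of an array, 3.53 to 3.59. VPS1 kept its direction and call under every alternative; its fitted difference depends on the background. Leaving out 1 array gave 3530 to 4113 changed genes as deposited and 322 to 787 on the quantile scale, 451 to 500 and 145 to 184 at least 2-fold, and 19 to 22 and 17 to 20 lists; on the quantile scale the 24 genes with the largest changes were called each time, while 5 to 54 of the 202 genes under the naming rule lost their call and up to 4 gained one. From the deposited 4194 and 472 genes, quantile normalization gave 711 and 159, median centring 690 and 162, every probe set that is no control 8530 (more rows tested), and a log2 difference of at least 0.58 gave 2061. From the 711 and 159 on the quantile scale, the deposited values gave 4194 and 472, array weights 1285, the replicate block 1676, an unmoderated test 372, an adjusted p under 0.01 267, and a log2 difference of at least 0.58 gave 397. Among lists, an estimated correlation called 0 on both scales (6 at an unadjusted p under 0.05 on the quantile scale) and fry called 45 as deposited, 44 of them higher. The replicate block turned 22 named genes to called and ended the call of the pleiotropic drug resistance list (adjusted p = 0.0727), and it changed no other call of a named gene or list. Of the 19 lists called on the quantile scale, fry did not call those of endocytosis, ribosome biogenesis, induced stress genes, phosphate, amino acids and Hog1 targets, and the deposited values did not call those of induced stress genes, phosphate, autophagy and Hog1 targets. Fry also called the copper, dynamin, pheromone signalling, flocculation and DNA damage lists, and array weights the nitrogen list. On the deposited values, which hold the shift of about 0.5, these differences, called on at least 1 of the scales, reversed: MF(ALPHA)2 0.50, STE2 0.049, HIS3 0.38, MGM1 0.048, PEX2 0.044, VPS75 0.053, VTH1 0.065, VMA7 0.31, PKR1 0.31, VMA16 0.39, FLO11 0.17, STE12 0.061, FUS3 0.0088, RPS14B 0.32, NOP13 0.033, UTP8 0.11, ARX1 0.11, HSC82 0.17, BLM10 0.31, RPT2 0.32, CDC48 0.33, PRE2 0.33, ZRC1 0.12, HIS1 0.011, AVO2 0.090, RGT2 0.060, NTH2 0.33, FIG2 0.13, CNA1 0.14, BAS1 0.076 and GEA1 0.086. The Hog1 list, with a mean of 0.81 as deposited, was not called there (camera adjusted p = 0.919). Its test had the opposite sign there, and the cause was not tested. The list of VPS1 and its neighbours was called lower by fry, with a mean of -1.25 that includes VPS1 itself at -7.69. Its median was 0.20, and 4 of its 5 members lay above 0.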

Other observations

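The genes of the next sentences belong to lists drawn up after values were seen. Eisosome and MCC domain genes, which shape furrows of the plasma membrane, numbered 14, of which 10 did not pass. FHN1 rose by 3.24 ± 0.27 (log2, SE, n = 3 per strain) and PUN1 by 0.97 ± 0.18, while NCE102 fell by 1.33 ± 0.21 and SUR7 fell by 0.97 ± 0.14. Of 10 genes for catabolism of aromatic and branched amino acids 3 rose, the phenylpyruvate decarboxylase ARO10 by 2.71 ± 0.21, the acetyltransferase ATF2 by 1.73 ± 0.15 and the aminotransferase ARO9 by 1.19 ± 0.18, and ATF1 fell by 0.61 ± 0.15.

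The other lists fixed before the data were examined were not called. DNA damage genes rose in 2 of 24 cases, with HUG1, an inhibitor of ribonucleotide reductase, up by 1.03 ± 0.14 (log2, SE, n = 3 per strain), and adjusted over the list alone also 2 rose, while 5 rose with the replicate number as a block (camera adjusted p = 0.0720; called on ranks, adjusted p = 0.0376, by fry, 0.0488, with each array centred on its median, 0.0462, and without vps1 deletion replicate 2, 0.0437). Nitrogen catabolite repression genes rose in 4 and fell in 1 of 38 cases, the ammonium permease MEP1 by 0.96 ± 0.12, the same adjusted over the list alone and 10 and 3 with the block (adjusted p = 0.118, and 0.0301 without wild type replicate 1). Copper genes rose in 2 and fell in 1 of 12 cases, 3 and 2 adjusted over the list alone and 4 and 2 with the block (adjusted p = 0.254), with CUP2, a copper-sensing transcription factor, up by 1.14 ± 0.11. Golgi and secretory genes rose in 3 and fell in 1 of 60 cases, 1 and 1 adjusted over the list alone and 9 and 2 with the block (adjusted p = 0.217; median -0.0031, mean 0.058), STE13 by 0.78 ± 0.10. Flocculation and filamentation genes fell in 5 of 15 cases, and adjusted over the list alone 5 fell and 3 rose, and 6 and 3 with the block (adjusted p = 0.311); PHD1, a transcription factor of filamentous growth, fell by 0.90 ± 0.13. Zinc genes rose in 2 and fell in 1 of 26 cases, the same adjusted over the list alone and 5 and 3 with the block (adjusted p = 0.355), NRG2 by 1.30 ± 0.18. Oxidative stress targets rose in 4 and fell in 2 of 38 cases, the same adjusted over the list alone and 6 and 6 with the block (adjusted p = 0.542), with the peroxiredoxin TSA2 up by 2.70 ± 0.30. Thiamine genes rose in 4 and fell in 2 of 19 cases, 4 and 3 adjusted over the list alone (adjusted p = 0.906; median and mean below 0, direction of the test above), and the thiamine transporter THI7 fell by 1.06 ± 0.09. Genes of the G1 and S phases rose in 2 and fell in 1 of 43 cases, 0 and 1 adjusted over the list alone and 2 and 5 with the block (adjusted p = 0.541), and the cyclin CLB5 fell by 0.76 ± 0.15. Glycolysis and trehalose and glycogen genes rose in 1 of 28 and 1 of 26 cases, 0 adjusted over the list alone; with the block 1 rose and 7 fell in the former and 3 rose and 2 fell in the latter (adjusted p = 0.461 and 0.636).

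An extra copy of chromosome XI is a hypothesis for the higher PAP1 and OSH6 beside the deleted gene, tested after their values were seen. The median log2 difference of the chromosome's genes was -0.033, against at least 0.5 if the chromosome were gained, and the medians of the chromosomes lay between -0.065 and -0.0021. A local effect of the deletion on these neighbours may remain, which no test here addressed.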
